A study of Homo sapiens with 2 samples.

How the data were processed

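The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of MCF10A cells, a non-transformed human mammary epithelial line, that express Flag-tagged YAP-5SA. YAP is the transcriptional co-activator restrained by the Hippo pathway, and 5SA is an active mutant in which the serines phosphorylated by LATS kinases are replaced by alanine. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication, Flag-bound chromatin was collected on Flag-M2 beads, and libraries from the ChIP DNA and from input DNA were amplified by PCR and sequenced on an Illumina HiSeq instrument. There was 1 ChIP library and 1 input library. The ChIP library came with 1 peak file, and reads or coverage of the input were not analysed here.

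The submitters' processing notes name BWA 0.6.1, MACS and the build hg19. The MACS version, its threshold, any filtering of duplicate reads and the use of the input as its control are not given in the sources used here. Per the file headers, the deposited peak file has a summit track and an interval track. The summit track gives each peak's summit position and a score, and the interval track gives its start and end. The score deposited by the authors is called the height below. It is a whole number for all 9393 peaks, and its unit and scaling are not stated, so it was used only to describe and rank peaks within this list. Summit and interval lines were joined by their order: all 9393 summits lay on the chromosome of their interval, and 100% lay inside it. Summits fell on multiples of 32 bp for 80.4% of peaks and 16 bp from such a multiple for 18.9%, so positions are resolved to about 32 bp. The remaining 69 summits lay elsewhere.

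Sequencing depth is unknown, because the file gives no read counts. No interval that needs a read count was computed. With 1 ChIP library, nothing has a replicate check, no p-value is given, and every interval, draw or shuffle describes this peak list rather than the spread between cultures. Peaks are not replicates.

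Before the data were examined, the plan covered the peak set, its location relative to genes, distance to transcription start sites, TEAD and other motifs, and 19 gene lists, with a rule for naming genes. All but the peak set need an hg19 genome or annotation, which was not used here. The gene table at hand is for GRCh38, and coordinates of different builds were not mixed, so no peak was assigned to a gene, no gene is named, and regions are given by hg19 position. The comparisons between chromosomes and regions were added after the file had been seen.

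Positions are 1-based. The length of a chromosome was taken as the distance from its first to its last summit less its longest peak-free stretch, because hg19 chromosome lengths and assembly gaps were not used here. For the density on each side of a height split, no stretch was left out. Intervals at the 95% level for densities, density ratios and mean or median heights come from 2000 bootstrap draws of 5 Mb blocks. Those for isolated and trimmed peaks resample single peaks. Wilson intervals at the same level accompany shares of peaks and cover counting error only. A chromosome's mean height was set against 10000 random draws of as many peaks from the whole list, and against 10000 stretches of as many consecutive peaks begun at random places along the genome, which keeps neighbours together. Windows of 5 Mb with 10 or more peaks were compared with 10000 random draws. Each chromosome was also split where the mean log2 height differed most relative to its standard error, with at least 40 peaks on each side, and the statistic was compared with 1000 shuffles of the heights, singly and in runs of 5 neighbours. The same split was applied to counts of peaks per 1 Mb window, with at least 20 windows on each side. Spacing was compared with 1000 uniform random placements of the summits on the same lengths, and with 200 placements that kept the number of peaks in each 5 Mb. Intervals at most 12.5 kb apart were joined into groups. Correlations of log2 height between peaks on the same chromosome were compared with 200 shuffles. For these, heights were standardized over the whole list, not within each chromosome.

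The split was tested on simulated data: heights of the whole list were placed at random on the 755 peaks of chromosome 5, and a factor of 1.2 was added on 1 side. In 20 of 20 simulated sets the split exceeded all 100 shuffles, and in 18 it lay within 10 Mb of the true place. Without the factor, 1 of 20 sets exceeded all shuffles. The simulated heights were independent between neighbours, and no other chromosome was simulated. The rates may therefore differ for the real heights and for chromosomes with fewer peaks. Alternatives were a restriction to the 4278 peaks higher than the median, merging of overlapping peaks, other lengths, other joining distances, other shuffles and regions left out. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.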

Results

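To map the genomic sites bound by active YAP, Flag-tagged YAP-5SA was immunoprecipitated from MCF10A cells and the recovered DNA was sequenced. The 2 samples were 1 ChIP library and 1 input DNA library, each without a replicate. The peak list called by the authors from the ChIP library is described here. Its read depth is unknown, and each value below carries the counting and placement error within that list only.

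The list held 9393 peaks on all 22 autosomes and chromosome X, which together covered 6.03 Mb of hg19. Peaks were narrow, with a median width of 611 bp, an interquartile range of 520 to 709 bp and extremes of 215 and 2669 bp. Summits lay a median of 42.5 bp from the middle of their interval. The height at the summit, which is the authors' score with no unit given, had a median of 24, an interquartile range of 19 to 30 and a mean of 25.8 ± 9.60 (SD over 9393 peaks). Heights ran from 9 to 100, with 814 peaks (8.67%) at 40 or more and 88 at 60 or more.

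**Figure D1:**
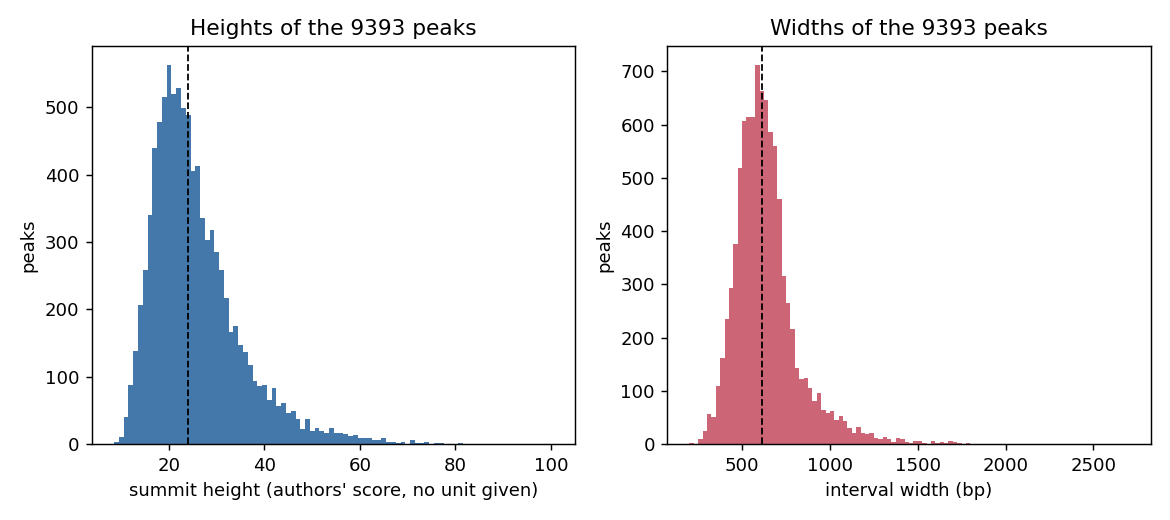
Distribution of summit height (left, authors' score, 1 unit per bin) and interval width (right, bp, 25 bp per bin) over the 9393 peaks, with peaks per bin on the vertical axes and dashed lines at the medians of 24 and 611 bp. Both distributions have a single mode and a tail to the right, to 100 in height and 2669 bp in width.

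Wider peaks were taller on the whole. The narrowest 20% of peaks, from 215 to 501 bp, had a median height of 22 and 2.91% of its peaks at 40 or more. The widest 20%, from 740 to 2669 bp, had a median height of 25 and 14.9% of its peaks at 40 or more. The relation was weak across peaks, which are not independent replicates (Spearman's rho = 0.15). It also did not extend to the lowest peaks: the 142 peaks of height 12 or less had a median width of 681 bp, against 571 bp for the 2126 peaks of height 19 to 22. The widest interval lay on chromosome 8 from 128234681 to 128237349, with a height of 33.

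The tallest peak lay on chromosome 19 from 3116252 to 3116834 and had a height of 100. The next was on chromosome 10 from 73526371 to 73527417, with a height of 99. Chromosome 20 held the third, from 60936194 to 60937782 with a height of 91, and the fourth, from 21706454 to 21707107 with a height of 82. A height of 81 was reached on chromosome 10 from 73839941 to 73840878 and from 99334158 to 99335047. A height of 77 was reached on chromosome 1 from 144989173 to 144990099 and on chromosome 7 from 28080772 to 28081623. The peaks on chromosome 3 from 58546434 to 58547012 and on chromosome 5 from 148292323 to 148293204 both had a height of 76. Of the 20 tallest peaks, 5 were on chromosome 10, and 4 of these lay between 73 and 75 Mb. That region held 26 peaks with heights from 17 to 99 and a median of 32. An adjacent pair of its tall peaks, of heights 81 and 74, was separated by 35 bp.

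**Figure D2:**
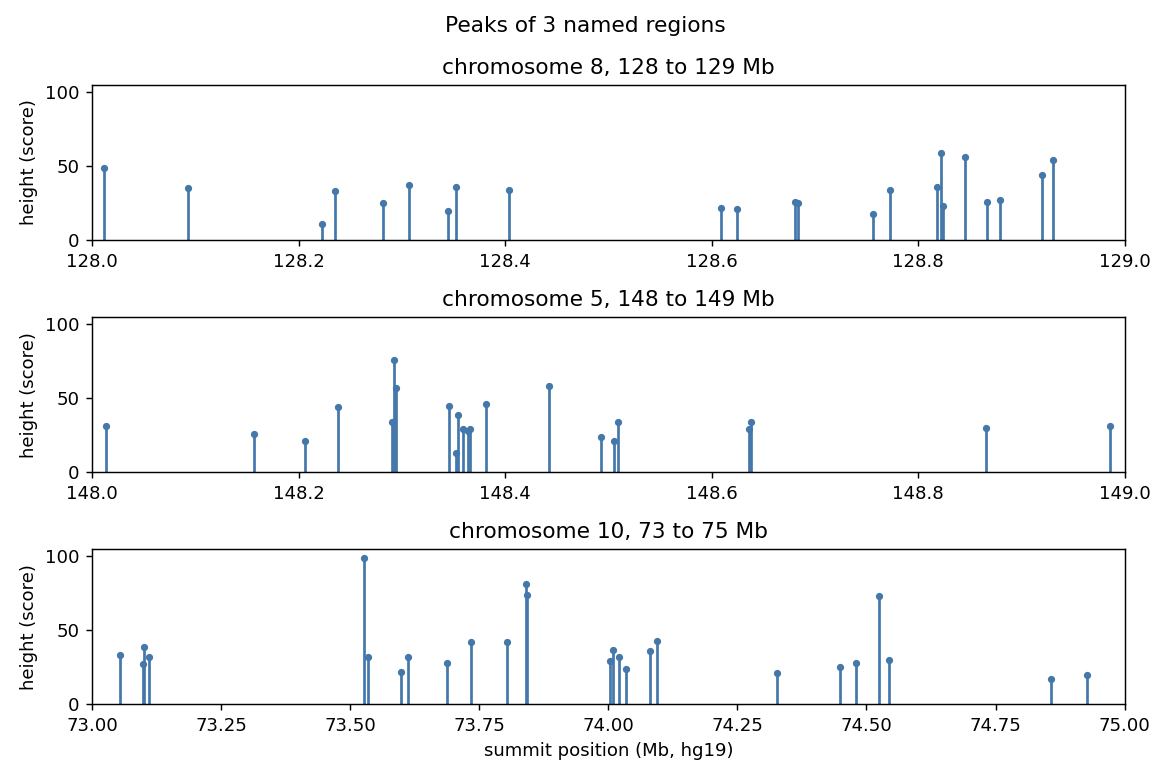
Summit heights (vertical axis, authors' score) against summit position (horizontal axis, Mb, hg19) for every peak on chromosome 8 from 128 to 129 Mb, chromosome 5 from 148 to 149 Mb and chromosome 10 from 73 to 75 Mb, with 1 stem per peak. The first region holds 23 peaks up to a height of 59, the second 22 peaks up to 76, and the third 26 peaks up to 99.

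Peaks were spread unevenly between chromosomes. Neither number nor height was corrected here for DNA copy number. A difference between chromosomes or regions, here and below, is therefore not by itself a difference in binding. Chromosome 20 had 355 peaks, or 6.07 per Mb (95% interval 5.48 to 6.63), against 3.40 per Mb over all other chromosomes, a ratio of 1.79 (1.61 to 1.95). Chromosome X had 165 peaks, or 1.18 per Mb (0.84 to 1.56), against 3.58 per Mb over the autosomes, a ratio of 0.33 (0.23 to 0.44). The lowest autosome, chromosome 16, had 2.45 per Mb (1.79 to 3.11), and the median autosome had 3.46. Chromosome 1 had 4.50 per Mb (3.99 to 5.02) and chromosome 5 had 4.33 (3.50 to 5.21).

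Peaks of chromosome 20 were also taller. Their mean height was 29.5 (95% interval 28.5 to 30.6) against 25.6 elsewhere, and 14.9% of them were 40 or more in height against 8.42% elsewhere. None of 10000 random draws of 355 peaks had a mean as high, and 13 of 10000 stretches of 355 consecutive peaks, which may overlap chromosome 20 itself, did. Chromosome 22 had 15.7% of its 121 peaks at 40 or more and a mean of 27.4 (26.6 to 28.6), which 312 of 10000 draws reached. Chromosome 19 had a mean of 27.2 (25.1 to 28.8), which 143 draws reached. Chromosome 1 had a mean of 26.5 (25.8 to 27.2), which 96 draws and 1280 of 10000 stretches of consecutive peaks reached. Chromosome 5 had a mean height of 26.8 (25.5 to 28.0), which 14 of 10000 draws of single peaks reached. Stretches of 755 consecutive peaks reached it in 1187 of 10000 cases. These stretches may overlap chromosome 5 itself or hold chromosome 20, so they cannot show whether the mean of chromosome 5 stood apart. Low means were found too. Chromosome 6 had a mean of 24.5 (23.9 to 25.2), which 9992 of 10000 draws and 9477 of 10000 stretches reached. The means of chromosomes 13, 2 and 4 were 24.2, 24.9 and 24.7, reached by 9979, 9965 and 9954 draws. The mean height of chromosome X, 25.6 (24.1 to 26.7), was reached by 5847 of 10000 draws and did not stand apart despite the low number of peaks.

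**Figure D3:**
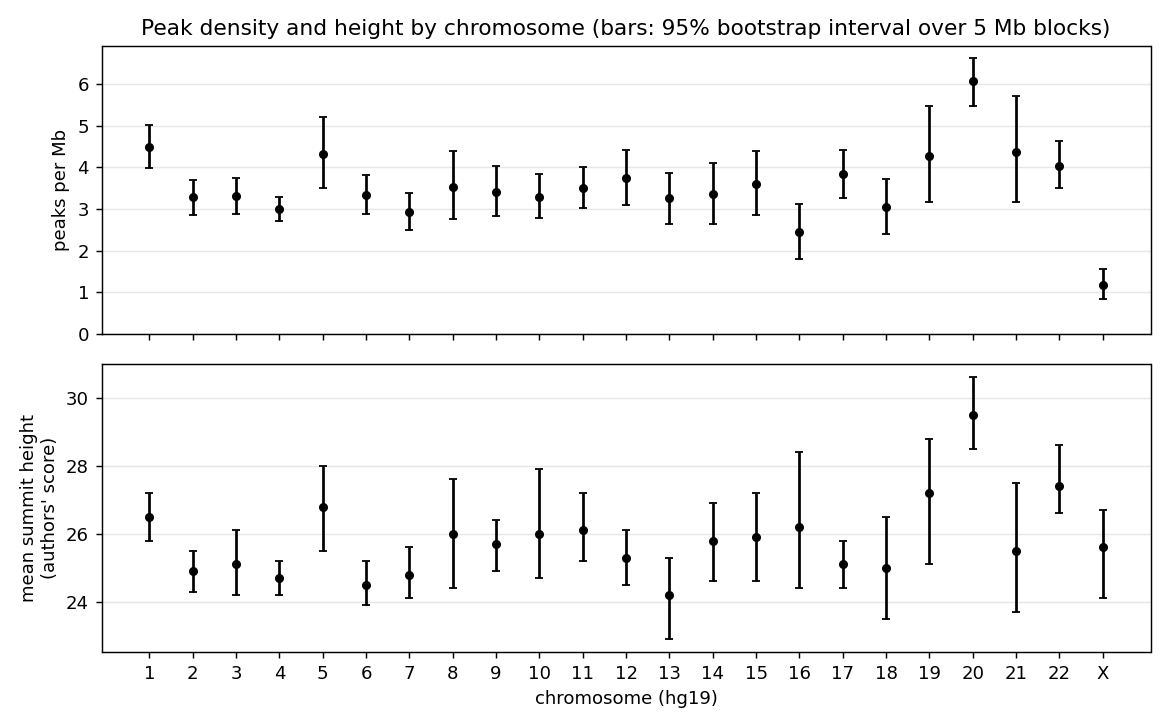
Peaks per Mb (top) and mean summit height in the authors' score (bottom, axis not starting at 0) for each hg19 chromosome, with points for the value and bars for the 95% bootstrap interval over 5 Mb blocks. Chromosome 20 lies highest in both, at 6.07 peaks per Mb and a mean height of 29.5, and chromosome X lies lowest in density at 1.18.

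Within chromosomes, the clearest change was on chromosome 5. Its heights divided best between 119.4 and 119.8 Mb: the 350 peaks before had a mean height of 24.1 ± 8.16 (SD over peaks) and the 405 peaks beyond had 29.2 ± 11.3, a difference of 5.08. Peak density was 2.93 per Mb before and 6.63 per Mb beyond. The length before the split keeps the longest peak-free stretch, from 43.8 to 49.9 Mb, which lowers the first value. None of 1000 shuffles of the heights, singly or in runs of 5 neighbours, gave a split as large. Chromosome 8 divided between 126.6 and 127.4 Mb, with a mean height of 24.9 ± 8.60 over 398 peaks before and 30.2 ± 12.9 over 99 peaks beyond. No single shuffle and 4 of 1000 run shuffles were as large. This split depended on the window from 125 to 130 Mb, which contains it. Without that window, the means were 24.9 and 26.5, with 55 peaks beyond, and 450 of 1000 shuffles gave as large a best split. The window was picked for the highest mean height on the chromosome, so a weaker split was to be expected. Of the 23 chromosomes, only 5 and 8 had a split that at most 10 of 1000 single shuffles matched. The power to find a split on chromosomes with fewer peaks was not examined. By chance about 0.253 chromosomes would, if heights were independent along the chromosome.

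On chromosome 1 the density, not clearly the height, differed along its length. Before the peak-free stretch from 120.1 to 144.0 Mb there were 441 peaks at 3.69 per Mb, and after it 568 peaks at 5.40 per Mb, a ratio of 1.46 (95% interval 1.22 to 1.80). Mean heights were 25.7 and 27.0, a difference of 1.26 with an interval of -0.07 to 2.66. The same comparison across the longest peak-free stretch of each of the 20 chromosomes with at least 40 peaks on both sides gave ratios whose intervals lay above 1 on chromosomes 1 and 5, the latter with a ratio of 1.44 (1.03 to 2.03). Intervals lay below 1 on chromosome 6, with a ratio of 0.65 (0.50 to 0.85), and on chromosome 13, with a ratio of 0.78 (0.58 to 0.96). Mean height after the stretch less that before it was 3.95 (2.27 to 5.55) on chromosome 5, -1.71 (-3.03 to -0.56) on chromosome 6 and -3.19 (-5.03 to -1.06) on chromosome X. On the other 17 the intervals included 0. No allowance was made for the number of ratios and differences compared, so some of these intervals may miss 1 or 0 by chance.

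**Figure D4:**
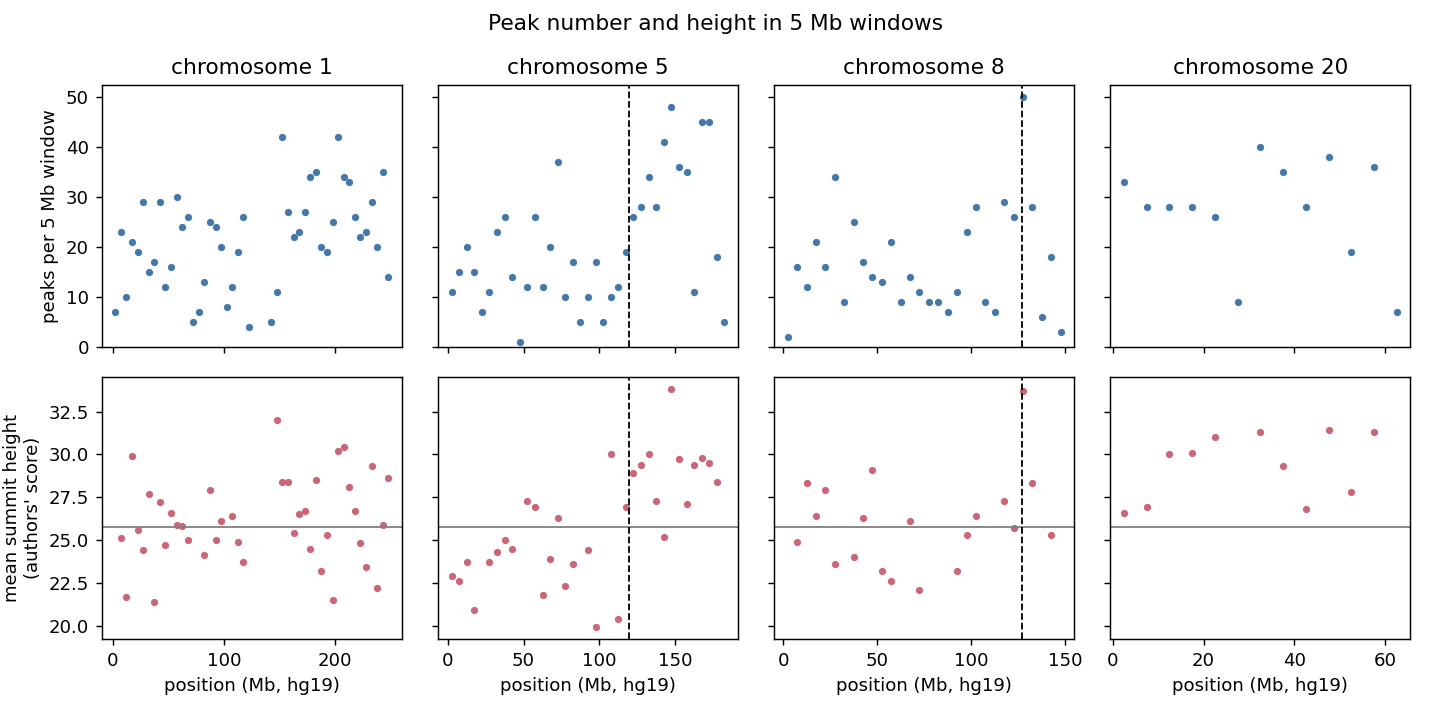
Peaks per 5 Mb window (top) and mean summit height in the authors' score for windows with 10 or more peaks (bottom, axis not starting at 0) along chromosomes 1, 5, 8 and 20, 1 point per window and position in Mb of hg19. The grey line is the mean of all peaks, 25.8, the dashed lines mark the best height splits of chromosomes 5 and 8, and all 11 windows of chromosome 20 lie above the mean; windows at chromosome ends are partly outside the chromosome.

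Among the 454 windows of 5 Mb with at least 10 peaks, the highest mean height was on chromosome 10 from 70 to 75 Mb, at 37.0 ± 19.9 (SD over 29 peaks). Chromosome 5 from 145 to 150 Mb followed with 33.8 ± 13.9 over 48 peaks, and chromosome 8 from 125 to 130 Mb with 33.7 ± 13.9 over 50 peaks. None of 10000 random draws of as many peaks reached any of these 3 means. In all, 7 windows were reached by at most 10 draws, and 3 of them were on chromosome 20. If heights were independent along the genome, 0.499 windows would be expected. Heights of nearby peaks were weakly correlated, and no comparison that keeps neighbours together was run for the windows.

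Peaks lay closer together than random placement gave. A neighbouring summit within 10 kb was found for 1836 peaks, or 19.5% (95% Wilson interval 18.8 to 20.4), against a mean of 6.99% over 1000 uniform placements, the highest of which gave 8.07%. Placements that kept the number of peaks in each 5 Mb gave a mean of 7.65%. Within 50 kb the share of peaks with a neighbour was 47.8% (46.7 to 48.8) against 30.3% over the uniform placements. Uniform placements left out only the longest peak-free stretch of each chromosome, so they could fall where reads may not map. In the list, 78 interval pairs lay under 200 bp apart, and whether such pairs are single enrichments was not examined. The single megabase with most peaks was on chromosome 8 from 128 to 129 Mb, with 23 peaks and a median height of 33. Chromosome 5 followed with 22 peaks from 148 to 149 Mb, of median height 31, and 20 peaks from 142 to 143 Mb, of median height 22.5. The highest count in any megabase over the 1000 placements was 18.

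When intervals at most 12.5 kb apart were joined, 2170 peaks (23.1%) fell into 964 groups of at least 2, of which 40 held 4 or more. These counts depended on the joining distance: at 5 kb 13.7% of peaks fell into groups, 7 of which held 4 or more, and at 25 kb 33.9% did, with 94 such groups. At 12.5 kb the largest groups held 7 peaks, on chromosome 19 from 39127338 to 39157242 and on chromosome 1 from 228716985 to 228742635. Groups of 6 lay on chromosome 3 from 134027234 to 134053014, with a tallest peak of 53, and on chromosome 5 from 148344982 to 148366609, with a tallest peak of 45. Grouped peaks had a mean height of 26.7 ± 10.3 (SD over 2170 peaks) and single peaks 25.5 ± 9.35 (SD over 7223 peaks), a difference of 1.18 (95% interval 0.70 to 1.70).

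Long stretches without peaks were also found. There were 22 over 5 Mb, and 6 of these were on chromosome X. The longest ran from 38.7 to 71.3 Mb on chromosome 9, from 120.1 to 144.0 Mb on chromosome 1 and from 31.2 to 47.9 Mb on chromosome 16. Whether reads could be mapped in these stretches was not examined, so the absence of a peak there is not evidence that YAP-5SA was absent.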

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

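No paired analysis was possible because there is 1 library per group and the labels give no replicate numbers, and no replicate could be left out. Of the alternatives fixed before the data were examined, restriction to peaks higher than the median left 4278 of 9393 peaks, by construction. Merging overlapping peaks and keeping only chromosomes 1 to 22 and X removed none, because the closest intervals are 3 bp apart and no other chromosome is listed. Those for location, distance to transcription start sites, motifs and gene lists were not run, because no hg19 genome or annotation was used. The remaining alternatives were chosen after seeing the data. The density ratio of chromosome 20 to the rest was 1.79 with the full span as the length, as with the main length, and 2.62 for peaks higher than the median. Because the peaks of chromosome 20 are taller, that restriction was bound to raise its ratio, so 2.62 mixes height with density. The density ratio of chromosome X was 0.33 and 0.31 under the same alternatives. The density ratio across the longest peak-free stretch of chromosome 1 was 1.63 for peaks higher than the median, against 1.46. The share of peaks with a neighbour within 50 kb was 1.58 times that of uniform placement, 1.49 times that of placements keeping the number of peaks in each 5 Mb, and 1.94 times for peaks higher than the median. Joining at 5 kb gave 604 groups with 13.7% of peaks, and at 25 kb 1352 groups with 33.9%, against 964 groups with 23.1%. The height split of chromosome 5 was matched by 0 of 1000 shuffles also without 145 to 150 Mb, while that of chromosome 8 was matched by 450 without 125 to 130 Mb. Each window left out was picked for the highest mean height on its chromosome. The correlation of heights 10 to 20 Mb apart was 0.001 without chromosomes 1, 5, 8, 10 and 20, which had been picked for their heights. The mean height of grouped less single peaks was 1.14 (95% interval 0.52 to 1.73) without the same chromosomes, against 1.18. None of these directions reversed. Unknown read depth and the single library limit all of these values.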

Other observations

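The tests of chromosome 20 on isolated peaks and on peaks without the tallest 10%, and that of the correlation of heights 10 to 20 Mb apart, were written before their results were seen. The tests of the windows of chromosome 20, the count splits, chromosome X and the low, wide peaks were chosen after the values had been seen. The immunoprecipitated library has no replicate, so every pattern below belongs to this peak list.

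Over the whole list, heights of nearby peaks were weakly correlated. The correlation of log2 height was 0.115 between peaks under 0.01 Mb apart, where shuffled heights gave -0.066 to 0.063, and 0.046 between peaks 0.2 to 1 Mb apart (shuffled -0.011 to 0.012). It was still 0.021 between peaks 10 to 20 Mb apart (shuffled -0.004 to 0.004) and 0.017 at 20 to 40 Mb. Heights were standardized over the whole list, so differences in mean height between chromosomes and between long regions enter these values at every distance. The values at long distances are therefore not evidence separate from the chromosome and regional differences given above. Without chromosomes 1, 5, 8, 10 and 20, which were chosen after their heights had been seen, the value was 0.050 under 0.01 Mb (shuffled -0.061 to 0.085), 0.033 at 0.01 to 0.05 Mb (-0.057 to 0.047) and 0.009 at 0.05 to 0.2 Mb (-0.031 to 0.031), all inside the shuffled range. It stayed above that range only at 0.2 to 1 Mb, at 0.020 (-0.012 to 0.013), and was 0.001 at 10 to 20 Mb (-0.004 to 0.005). Since these chromosomes were picked for their heights, a fall was to be expected, and the pairs under 0.01 Mb fell from 1128 to 717. The removal of 5 other chromosomes was not run, so the correlation is not assigned to these 5. Uncorrected DNA copy number of the cell line is a candidate explanation of a correlation at such distances. Regional differences in binding would also give one and were not tested. These are correlations across pairs of peaks, which are not independent replicates.

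The values argue against close groups of peaks, and against a few extreme peaks, as the whole source of the taller peaks on chromosome 20. Among peaks with no other peak within 50 kb, the median height was 27 on chromosome 20 and 23 elsewhere, a difference of 4 (95% bootstrap interval 2 to 5). Over all peaks the medians were 27 on chromosome 20 and 23 elsewhere, and a median is little moved by a few extreme peaks. Without the tallest 10% of peaks on either side, the medians were 26 and 23, a difference of 3 (2 to 5). This trimming could change the medians little and adds little to them. Extra DNA copies of the whole chromosome, not corrected in the heights, were left open. All 11 windows of chromosome 20 had a mean height, from 26.6 to 31.4, above the 25.6 elsewhere, as against 45.4% of windows on other chromosomes. The best height split of chromosome 20 set its first 42 peaks, up to 5.6 Mb, at a mean of 25.3 and a median of 22.5, no higher than elsewhere, against 30.1 and 28 for the 313 peaks beyond. Density went the other way, with 7.40 peaks per Mb before the split and 5.55 beyond, both above the 3.40 of other chromosomes. The length used for 5.55 keeps the longest peak-free stretch, from 26.1 to 30.1 Mb, while such stretches were left out for 3.40. The value beyond the split is therefore too low on that measure, and the fall in density is overstated. Of 1000 shuffles, 20 single and 50 run shuffles gave as large a split. The split was picked from the heights, and this condition was added after its value had been seen. The best count split lay at 22 Mb, and 889 single and 790 run shuffles were as large. With 56 windows and at least 20 required on each side, it could not find a change in density near 5.6 Mb. Stronger or more frequent binding of YAP-5SA along chromosome 20 would also raise the heights and was not tested, since the coverage of the input was not analysed here.

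On chromosome 5, counts of peaks per Mb, split without use of the heights, changed at 119 Mb, from 3.07 to 6.61, and none of 1000 single shuffles and 2 of 1000 run shuffles of the windows gave as large a change. This place is 0.6 Mb from the height split. The 2 measures are not independent. The densities on both sides of the height split, 2.93 and 6.63 per Mb, had been seen before this test was chosen, and a taller signal also lifts more peaks over the calling threshold. The agreement therefore does not single out a step in DNA copy number, not corrected in the heights, which was left open, as was a region denser in YAP-5SA target enhancers, which was not tested. On chromosome 8 the count split lay at 117 Mb, 10.0 Mb from the height split, and 17 of 1000 single shuffles and 123 run shuffles were as large. On chromosome 1 counts changed at 150 Mb, from 3.60 to 5.57 per Mb, which none of 1000 single shuffles and 5 run shuffles matched, whereas the best height split of that chromosome was matched by 399 single shuffles of the heights.

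Chromosome X had few peaks, and their median height of 23 was the lowest of any chromosome, shared with 11 of 22 autosomes. The other 11 autosomes had medians up to 27 and none was below 23, while 10 autosomes had a mean height at or below that of X. A uniformly lower signal that leaves only part of the peaks above the calling threshold was not excluded. The bound first set for it counted ties, and heights are seen only for peaks that passed the threshold. A smaller number of bound sites was left open too, as were a difference between the copies of X, and low mappability. No biological explanation was tested. The 56 peaks beyond the stretch from 82.0 to 93.7 Mb had a mean height of 23.5 and the 109 before it 26.7, a difference of -3.19 (95% interval -5.03 to -1.06). It was 1 of 20 chromosomes compared in this way, without allowance for their number.

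The lowest peaks were wide. The 14 peaks of height 10 or less had a median width of 780 bp. The 5th percentile of height was 13 in the widest 20% of peaks and 16 in the narrowest, a difference of -3 (95% bootstrap interval -3 to -2). This restates the pattern, so calling on the total signal under a peak was not tested by it. The calling threshold is not given in the sources used here, and no biological explanation was tested.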
